A study of Mus musculus with 7 samples.

How the data were processed

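Expression was measured by 3' mRNA sequencing in 7 libraries of sorted mouse cells, 3 in a table of fibroblast and fat pad libraries and 4 in a table of GFP and EpCAM sorts. The deposited values are whole-number counts per gene symbol with no normalization, as their values show. Per the submitters' processing notes, the tools were bcl2fastq, cutadapt, STAR, HTSeq and DESeq2 with the mm10 assembly, whose roles, settings and versions are not given in the sources used here. Per the labels, the second read carried a molecular identifier in every library and also a barcode in those of the first table. Whether the authors collapsed reads by identifier before counting is not given in the sources used here, so counts may hold amplification duplicates and the intervals cover counting error only. Strand handling and the treatment of reads shared by several genes are not given either, so genes with processed pseudogenes or overlapping neighbours are uncertain.

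The first table lists 24421 names and the second 13257, a shorter list. Names turned into dates by spreadsheet software (27 and 21, between 0.152% and 0.198% of a library's counts) name no gene and were left out of totals and comparisons. The symbols matched the reference symbols for 95.7% and 96.6% of genes, and positions were taken from the GENCODE annotation of GRCm38, the assembly that mm10 names. No count of a GFP or luciferase transgene or of a mitochondrially encoded gene was used here. Ribosomal protein genes took between 8.50% and 15.5% of the counts.

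Groups were taken from the labels, each with 1 library. The 7 comparisons, the gene rule, the gene lists and 6 alternative settings were fixed before the data were examined. As there is no spread between replicates, no test across samples was made and no p-value is given. For each gene with at least 20 counts summed over the compared libraries, the ratio of counts was scaled by TMM effective library sizes (edgeR 4.0.16, R 4.3.3) within its table. It was given the exact 95% Clopper-Pearson counting interval of the conditional binomial (scipy 1.17.1, Python 3.11.15). A gene was called higher or lower when that whole interval lay beyond 2-fold. A library at 0 was set to 3 counts, which makes the ratio a bound ("at least" or "no less than") that leaves out the counting error of the other library, though the call took that error in, and no ratio was taken when both libraries had 3 counts or fewer. List medians hold such bounds. For pCAF, the shallowest library, 3 counts are 7.48 normalised CPM, and for sCAF 1.13.

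For 37 gene lists, the median log2 ratio of the members passing the filter was set beside 10000 random lists of the same size matched on mean expression in 25 bins, where at least 5 members passed. This describes the libraries and is no test of the conditions. Genes in the text are, for each comparison, the 10 with the highest and the 10 with the lowest interval bound nearest to 1, leaving out predicted, clone-named, pseudogene and ribosomal protein names. To these were added, for a list described, up to 4 members with the largest counts and up to 2 more with the largest ratio in each direction, and markers of the sort. Some genes that this rule names are not reported here. Genes shared by both comparisons with NMF were listed by the smaller of their 2 ratios.

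The method was tested on simulated counts with 200 changed genes per comparison. Of genes changed 4-fold and 8-fold it recovered 56% and 82% for pCAF versus NMF (7965 genes), 78% and 89% for sCAF versus NMF (10048 genes) and 64% and 76% for pCAF versus sCAF (9246 genes). For the EpCAM contrast it recovered 85% and 93% in GFP+ cells (9100 genes) and 75% and 91% in GFP- cells (9501 genes). For the GFP contrast it recovered 75% and 91% in EpCAM- cells (9569 genes) and 84% and 92% in EpCAM+ cells (9229 genes). There was 1 false call, in the EpCAM contrast of GFP- cells, and 0 in the other comparisons. The simulated libraries shared a single profile and, apart from the changed genes, varied by counting error only. At that error the rule makes almost no calls, so the few false calls were fixed in advance. They say nothing of spread between samples or of libraries that differ in most of their genes. The alternatives were DESeq2 size factors (DESeq2 1.42.0), total counts, ribosomal protein genes left out, at least 100 counts, no count filter, and a 4-fold rule. More were added after the data had been seen: factors without sCAF, the vascular, nerve, muscle and fat lists left out, and libraries thinned to 436051 or 1338608 counts.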

Results

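Bulk 3' mRNA sequencing was carried out on stromal and tumour cells sorted from the mammary fat pad of female BALB/c mice. The tumours were grown from 4T1 cells, a mouse mammary carcinoma line, after injection of 100000 cells into the fat pad, and were taken after 4 weeks from mice 12 weeks old. The first count table held 3 libraries: the normal mammary fat pad stroma of uninjected mice 8 weeks old (NMF), podoplanin-positive cancer-associated fibroblasts (pCAF) and podoplanin-negative cancer-associated fibroblasts (sCAF), all negative for the markers of erythroid (Ter119), leukocyte (CD45) and epithelial (EpCAM) cells. The second held 4 libraries from tumours of GFP-labelled 4T1 cells, depleted of Ter119 and CD45 cells and split by GFP and by EpCAM. Each group was 1 library, so no difference below has a replicate check, and the 95% intervals cover counting error only. The libraries totalled 436051 counts for pCAF, 2590144 for sCAF and 1161172 for NMF in the first table. In the second they totalled 1338608 for GFP- EpCAM-, 1717278 for GFP- EpCAM+, 1981977 for GFP+ EpCAM- and 2384264 for GFP+ EpCAM+.

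The sort markers followed the gates in most libraries. Pdpn, which encodes podoplanin, stood at 638 normalised CPM in pCAF and 54.4 in NMF, and had 0 counts in sCAF, which allows up to 1.13 CPM. Epcam stood at 413 CPM in GFP- EpCAM+ and 293 in GFP+ EpCAM+, against 35.7 and 26.0 in the EpCAM- sorts of the same GFP status. Ptprc, which encodes CD45, had 29 counts in GFP- EpCAM- and 0 or 1 in the other 6 libraries. Col1a1 stood at 14286 CPM in pCAF, 7617 in NMF and 84.8 in sCAF, and Krt18, a keratin of simple epithelia, at 39.9, 28.4 and 2869, in the same order. S100a4 stood at 344 in pCAF, 2656 in sCAF and 65.0 in NMF, Cd74 at 135, 300 and 11.4, Acta2 at 37.4, 3.01 and 0.812, and Krt8 at 24.9, 855 and 15.4. Acta2 rests on 15 counts in pCAF and 8 in sCAF, and its NMF level lies below the 3-count limit of 2.44 CPM. It did not reach the 20 counts needed for pCAF versus NMF and is not among the contractile genes compared there. On GRCm38, Pdpn lies on the minus strand of chromosome 4 (143267431 to 143299564), Epcam on the plus strand of chromosome 17 (87635979 to 87651129) and Col1a1 on the plus strand of chromosome 11 (94936224 to 94953042), all annotated as protein coding.

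**Figure D1:**
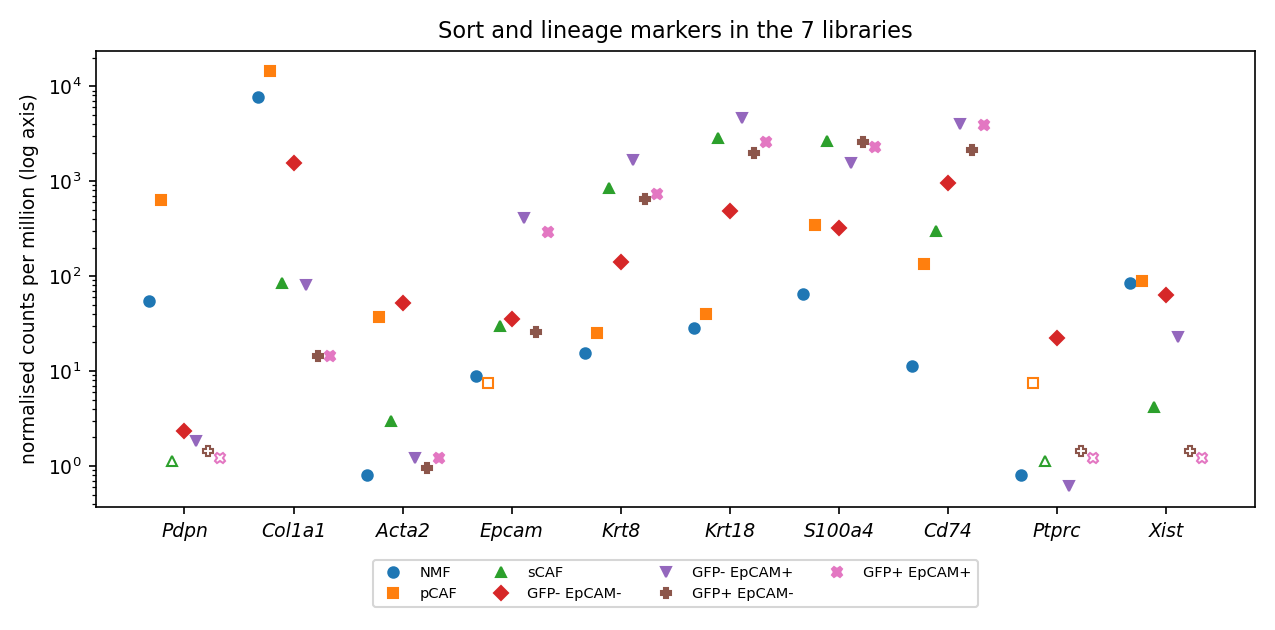
Normalised CPM (log axis) of 10 sort and lineage markers, 1 point per library; an open symbol is a library with 0 counts, drawn at its 3-count limit. Col1a1 stood at 14286 in pCAF and 84.8 in sCAF, and Krt18 at 39.9 and 2869; the 2 tables were scaled separately.

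The first comparison set the podoplanin-positive fibroblasts against the normal fat pad stroma. Genes of inflammatory fibroblasts were higher in pCAF: 14 of the 17 measured members of that list, with a median log2 ratio of 3.62 against -0.43 to 0.92 for 95% of random lists matched on expression. The acute-phase gene Saa3 was 2125-fold higher (95% counting interval 380 to 84047, on 1 count in NMF), the monocyte chemoattractants Ccl2 and Ccl7 148-fold (84.0 to 288) and 562-fold (99.6 to 22314), the neutrophil chemoattractant Cxcl1 40.9-fold (33.5 to 50.5) and Il6 155-fold (41.8 to 1298). Cxcl12 was the 1 member called lower, at 2.51-fold (2.14 to 2.97), and Csf1 and Nfkbia, at ratios of 0.699 (0.581 to 0.836) and 2.27 (1.97 to 2.601), met neither call. Endothelial genes were lower in pCAF, 19 of 20, with a median of -4.25. Pecam1 had 0 counts and was at least 44.6-fold lower, and Gpihbp1, the capillary protein that holds lipoprotein lipase, was at least 77.8-fold lower.

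Wound matrix and contractile genes were also higher in pCAF than in NMF. Of 14 matricellular genes 10 were higher and none lower (median 2.46), among them Spp1, which encodes osteopontin, 262-fold (127 to 655), Tnc 44.8-fold (29.1 to 72.5) and Bgn 6.39-fold (6.05 to 6.75), while Fn1 stood at 1.27-fold (1.22 to 1.33). Genes of the GFP+ tumour-cell sort moved with this group. The set was the 97 genes higher by the 4-fold rule in GFP+ than in GFP- EpCAM- cells of the second table. It was drawn up after the data had been seen, holds Spp1 and Mmp9, and is not limited to genes of tumour cells. Its median was 0.86 in pCAF relative to NMF (random range -0.55 to 0.23), with 16 of the 48 measured higher and 2 lower. Relative to sCAF, Spp1 and Mmp9 stood at ratios of 0.253 and 0.306 in pCAF, and Krt18 at 0.0139. A tumour-cell source of Spp1 and Mmp9 in pCAF was not tested. Of the cell cycle list, 3 of 6 were higher in pCAF (median 2.33, random range -1.65 to 0.68). Of 11 contractile genes 6 were higher and 1 lower (median 1.83): Tagln was 5.64-fold higher (4.74 to 6.73) and the smooth muscle gene Myh11 34.2-fold lower (6.01 to 1363). Matrix enzymes and their inhibitors split, with 10 of 20 higher and 1 lower (median 1.23): Mmp9 was 50.7-fold higher (13.0 to 436) and Timp1 44.4-fold (33.8 to 59.5), and Timp2 was 6.34-fold lower (5.59 to 7.21). The fibrillar collagens had 6 of 14 higher, led by Col12a1 at 55.3-fold (32.9 to 100.1), but their median of 0.99 lay inside the random range (-0.45 to 1.12), as did the fibroblast identity median of 0.64 (-0.34 to 1.06). Col1a2 was 2.54-fold higher (2.47 to 2.61) and Dcn 2.31-fold lower (2.19 to 2.43). The steady-state fibroblast list was lower (median -0.83, 5 of 20 lower and 1 higher), with Gsn 17.3-fold (15.7 to 19.1) and Igfbp6 5.71-fold lower (5.00 to 6.54).

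Other programmes differed between pCAF and NMF as well. The antigen-presenting class II genes Cd74, H2-Aa and H2-Ab1 were 11.8-fold (6.49 to 23.1), 10.9-fold (5.77 to 21.9) and 10.5-fold (5.41 to 21.9) higher, 3 of the 5 measured. They rest on 54, 46 and 41 counts in pCAF. H2-Aa also had 8213 counts in GFP+ EpCAM+ and 4198 in GFP+ EpCAM- tumour cells, and its source in pCAF was not tested. The glycolytic genes Pkm and Ldha were 4.61-fold (4.05 to 5.25) and 4.204-fold (3.64 to 4.85) higher, in a list with 6 of 15 higher, 1 lower and a median of 1.18. Slc16a3, a lactate exporter, was 99.0-fold higher (37.8 to 369), the steroid enzyme gene Hsd17b1 at least 92.1-fold and Calca at least 53.2-fold. Fat and nerve genes were lower: 9 of 14 adipocyte genes (median -2.51), with Fabp4 754-fold (135 to 29804), and 5 of 6 Schwann genes, with 1 higher (median -2.76). Inmt was 108.8-fold lower (42.4 to 400), and Cd300lg, Bcam, Esam and Rasip1 were at least 35.0-fold, 32.5-fold, 31.6-fold and 28.2-fold lower. Gapdh had 0 counts in pCAF against 545 in NMF, at least 59.2-fold, while Aldoa of the same pathway stood at 1.06-fold (0.907 to 1.23); Gapdh has many processed pseudogenes and its count is uncertain. The immediate early and dissociation list moved with these groups, 10 of 18 higher with a median of 1.33 (random range -0.32 to 1.03), led by Ier3 at 17.3-fold (14.8 to 20.2), and the cytosolic chaperone list had a median of 1.15 with 7 of 18 higher.

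By the 2-fold rule 616 genes were higher and 643 lower in pCAF than in NMF, of 8129 with at least 20 counts, so 48.9% of the calls were higher. Scaling to total counts alone gave 499 and 839 genes, or 37.3% higher, and moved the median log2 ratio of all genes from -0.20 to -0.41, while DESeq2 factors gave 53.1% higher (666 and 588), no count filter 56.5% (836 and 643), libraries thinned after the data had been seen 56.8% (551 and 419) and the 4-fold rule 57.3% (232 and 173). The fat pad and the tumours were digested with different enzymes and came from mice of different age.

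The second comparison set the podoplanin-negative library against the same normal stroma. All 17 fibroblast identity genes were lower in sCAF, with a median log2 ratio of -6.49 (random range -0.64 to 1.22), and 18 of 20 steady-state fibroblast genes, with a median of -8.88. Col1a1, Col1a2, Col3a1 and Dcn were 89.8-fold (78.7 to 103), 252-fold (206 to 311), 361-fold (286 to 462) and 471-fold (361 to 628) lower. Epithelial genes were higher, 13 of 16 with 1 lower and a median of 3.76, as were cell cycle genes, 18 of 19 with a median of 5.35. Krt18 was 101-fold higher (72.5 to 145), Krt8 55.4-fold (35.4 to 92.2), and the mitotic genes Top2a and Birc5 185-fold (51.2 to 1534) and 221-fold (39.5 to 8744).

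The genes lowest in sCAF relative to NMF were matrix and steady-state fibroblast genes. Igfbp6, Dpep1 and Sfrp4 had 0 counts and were at least 2932-fold, 1232-fold and 786-fold lower. Clec3b was 4287-fold lower (1186 to 35410.3), Dpt 3464-fold (1185 to 16804), Pi16 1986-fold (1007 to 4602), Tnxb 1645-fold (642 to 6042), Fndc1 2179.5-fold (603 to 18009), Igfbp5 1101-fold (558 to 2551) and Efemp1 2728-fold (489 to 107830). Complement genes were lower, 10 of 12 with a median of -5.74, among them C3 at 63.8-fold (54.7 to 74.7) and Serping1 at 112-fold (91.7 to 138). Endothelial genes were lower too, 17 of 20 with a median of -2.60, with Pecam1 3.20-fold (2.74 to 3.74) and Plvap 5.84-fold lower (5.20 to 6.58), as were 9 of 12 pericyte genes (median -1.99), 12 of 15 adipocyte genes (median -4.61), all 5 Schwann genes (median -6.60) and 4 of 6 skeletal muscle genes, with 1 higher (median -3.19). Of 5 mammary luminal genes 2 were higher and 1 lower, with a median of 1.61 that changed sign with no count filter. The genes highest in sCAF were Spp1 at 1038-fold (504 to 2583), Tnnt2 at 672-fold (121 to 26579), Wfdc2 at 97.2-fold (59.7 to 170.2), and, against 0 counts in NMF, the homeobox gene Rhox5 at no less than 193-fold and Padi4, Tns4, Msln, Insl6 and Podnl1 at no less than 171-fold, 134-fold, 129-fold, 111-fold and 80.6-fold.

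Class II genes were higher in sCAF in 6 of 6 cases (median 4.49), with Cd74 at 26.4-fold (15.6 to 48.5) and H2-Aa at 44.0-fold (25.6 to 82.9). Hypoxia and glycolysis genes were higher in 12 of 17 cases and lower in 1 (median 1.78), with Car9, the hypoxia-induced carbonic anhydrase, at 126-fold (22.5 to 5004) and Pkm at 6.56-fold (5.92 to 7.29). All 5 measured basal epithelial genes were higher (median 3.32), with Itgb4 at 10.4-fold (7.74 to 14.3). The inflammatory fibroblast list went both ways, 6 of 16 higher and 6 lower. The set of 97 tumour-cell genes moved with these groups, with 68 of the 91 measured higher, 6 lower and a median of 3.91 (random range -0.12 to 0.55), and the 911 genes lower by the 4-fold rule in GFP+ than in GFP- EpCAM- cells had a median of -3.77, with 511 of 636 lower. By the 2-fold rule 1561 genes were higher and 1695 lower, of 9815, so 47.9% of the calls were higher, against 32.8% with the 4-fold rule and 61.9% with at least 100 counts.

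**Figure D2:**
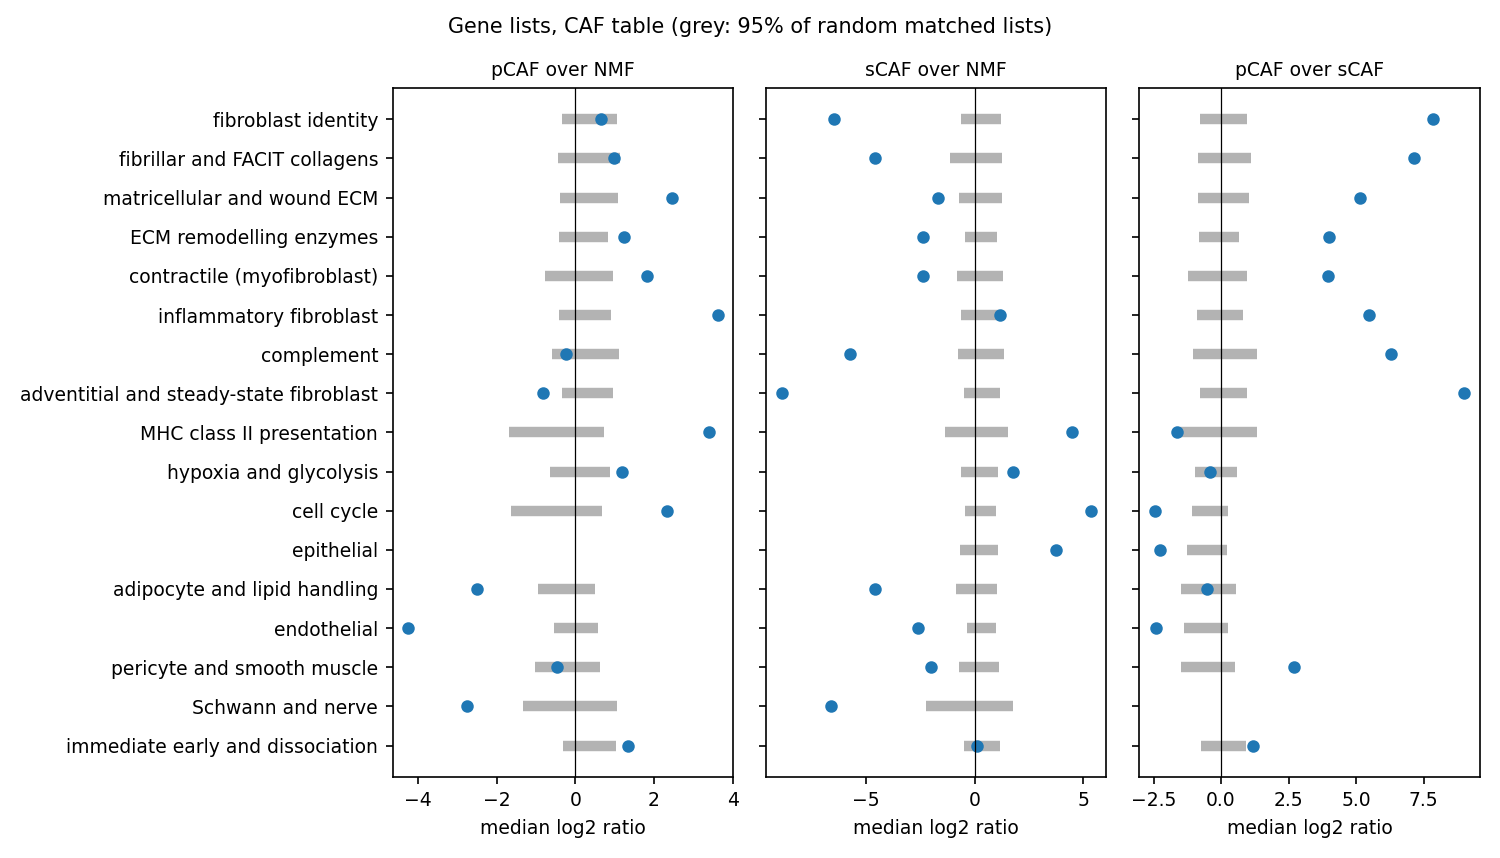
Median log2 ratio of each gene list (points) in the 3 comparisons of the first table, with the central 95% of random lists of the same size matched on expression (grey bars); lists with fewer than 5 measured members have no point, and the horizontal scales differ. Fibroblast identity lay at 0.64 in pCAF and -6.49 in sCAF, both relative to NMF.

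Of 7966 genes tested against NMF in both comparisons, 226 were higher in both the pCAF and the sCAF library, among them Spp1, Sphk1, Tfrc, Cxcl2, Slpi, Mmp9 and Runx1. Another 410 were lower in both, among them Inmt, Car3, Fmo1, Ntrk2 and S1pr1. Independent lists of these sizes would share 63.8 and 135 genes. The single NMF library served both comparisons, so part of the excess may come from that shared control: simulated unchanged libraries shared 0, but they vary by counting error only, at which the rule makes almost no calls, and so give no chance level for the overlap. There were 103 genes higher in pCAF and lower in sCAF, and 14 the opposite way. The sCAF library had all 17 fibroblast identity genes lower (median -6.49) and the same tumour-cell set at a median of 3.91, and it is named here by its label. Of the 226 genes, 15 belong to that set of 97, Spp1, Slpi and Mmp9 among them.

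The third comparison set the podoplanin-positive against the podoplanin-negative library. All 17 fibroblast identity genes and all 14 fibrillar collagens were higher in pCAF, with medians of 7.85 and 7.14 (random ranges -0.78 to 0.95 and -0.85 to 1.09). Lox, the collagen cross-linking enzyme, was 3844-fold higher (687 to 152091), Col3a1 691-fold (547 to 885) and Col1a2 638-fold (522 to 789), and Lum and Pdpn, at 0 counts in sCAF, at least 759-fold and 565-fold. Cell cycle genes were lower in pCAF, 14 of 20 with 1 higher and a median of -2.45, and epithelial genes 12 of 16 with a median of -2.24. Krt18 was 71.9-fold lower (44.3 to 126), Krt8 34.3-fold (18.6 to 71.6) and Top2a 6.71-fold (4.22 to 11.4). Endothelial genes were lower in pCAF too, 9 of 17 with 1 higher and a median of -2.40 (random range -1.36 to 0.24), of which 7 had 0 counts in pCAF and stand at their bound: Pecam1 was at least 13.96-fold lower, Plvap 5.92-fold (3.19 to 12.5) and Egfl7 10.7-fold (3.61 to 52.2), and Ramp2 was 5.87-fold higher (4.01 to 8.58). Pericyte and smooth muscle genes were split, with 6 of 10 higher and 2 lower (median 2.70). Des was 24.3-fold higher (13.5 to 46.2) and Pdgfrb, also on the fibroblast identity list, 6.62-fold (4.32 to 10.1). The 2 lower were Rgs5, at 0 counts in pCAF and at least 2.57-fold lower, and Mcam, 17.4-fold lower (3.06 to 692). Basal epithelial genes were lower in 4 of 5 cases (median -4.45), and the mammary luminal list had 3 of 5 lower and 2 higher (median -2.50, which changed sign with no count filter). The 97 tumour-cell genes had a median of -2.01 (random range -0.67 to -0.01), with 48 of 91 lower and 7 higher, and the 911 genes of the GFP- EpCAM- cells a median of 3.06, with 265 of 438 higher and 29 lower.

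Further genes at the head of this comparison were Pi16 at 1194-fold (604 to 2772), Dpt at 1758-fold (599 to 8542), Clec3b at 1836-fold (506 to 15198), Aebp1 at 908-fold (506 to 1822) and Sfrp4 at no less than 609-fold. Complement genes were higher in pCAF in 9 of 10 cases (median 6.30), with C3 at 44.9-fold (38.2 to 53.0). Inflammatory fibroblast genes were higher in 12 of 17 cases and lower in 1 (median 5.48): Cxcl14 stood at 797-fold (365 to 2180) and Ptx3 at 516-fold (140.5 to 4299), and Lif was 3.38-fold lower (2.11 to 5.77). Lower in pCAF were Wfdc2 at 127-fold (49.4 to 465), Ccnd1 at 58.6-fold (31.8 to 122), Itgb4 at 156-fold (27.9 to 6161) and Tnnt2 at 73.0-fold (24.9 to 354), and, at 0 counts, Gapdh, whose count is uncertain, Padi4, Hoxa5, Lad1 and Npnt at no less than 187-fold, 55.8-fold, 55.2-fold, 49.6-fold and 43.8-fold. By the 2-fold rule 1023 genes were higher and 1001 lower, of 8915, so 50.5% of the calls were higher. That share was 74.1% with the 4-fold rule (692 and 242 genes), 64.1% with no count filter (1784 and 1001), 62.3% with libraries thinned to equal depth, a setting added after the data had been seen (899 and 544), and 33.5% with at least 100 counts (419 and 831), so the balance depends on these settings. The median log2 ratio of all genes was -0.44 with TMM factors, -0.30 with DESeq2 factors and -0.60 with total counts.

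Levels were also ranked across 11839 genes listed in both tables, without taking any ratio between tables, since they were made and scaled separately. Across genes, which are not independent replicates, sCAF correlated with GFP+ EpCAM- at a Spearman rho of 0.88, with GFP+ EpCAM+ at 0.88, with GFP- EpCAM+ at 0.85, with GFP- EpCAM- at 0.69, with pCAF at 0.61 and with NMF at 0.60. For pCAF the highest of these values was 0.75, with NMF.

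The second table asked how EpCAM divides the GFP+ tumour cells. Epithelial genes were higher in EpCAM+ than in EpCAM- cells, 9 of 20 with a median log2 ratio of 1.41 (random range -0.18 to 0.20), as were basal epithelial genes, 3 of 7 with a median of 1.11. Epcam itself was 11.3-fold higher (8.55 to 15.2), Cldn4, a tight junction gene, 6.76-fold (6.10 to 7.49), Krt14 7.42-fold (6.51 to 8.48) and Lama3 11.7-fold (7.15 to 20.4). Krt18 and Krt8 stood at 1.299-fold (1.25 to 1.35) and 1.14-fold (1.06 to 1.22). The mesenchymal list had a median of -0.52 with no gene past the 2-fold rule, and Vim stood at 0.697-fold (0.682 to 0.712). The endothelial list had a median of -0.70 over 7 genes, none past the 2-fold rule.

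In EpCAM+ cells, Ly6c2 was 34.2-fold higher (13.1 to 127), Plekhs1 35.2-fold (9.45 to 296), Il17re 19.6-fold (6.42 to 97.1), Rab25 13.9-fold (7.12 to 30.9), Slc4a11 10.99-fold (7.43 to 16.9), and Ltf and Tspan1 at least 13.7-fold and 9.22-fold. The protease inhibitor Serpine2 was 22.2-fold lower (16.3 to 30.9), the acute-phase genes Saa3, Saa2 and Saa1 8.16-fold (5.58 to 12.3), 7.16-fold (3.50 to 16.5) and 7.75-fold (3.26 to 22.4), Wisp2 8.16-fold (5.34 to 13.0), Igfbp3 11.3-fold (4.90 to 32.2), Sod3 15.9-fold (5.06 to 80.4), F5 16.1-fold (4.05 to 140), Fbl 7.71-fold (4.27 to 15.1) and Gpihbp1 13.1-fold (3.23 to 115). Gpihbp1 rests on 2 counts in GFP+ EpCAM+ and 22 in GFP+ EpCAM-, against 942 in GFP- EpCAM- cells. Saa2 went the other way, with 54 counts in GFP+ EpCAM- and 0 in GFP- EpCAM- cells. The fibroblast identity list had a median of -1.19 in this contrast. A stromal source of such genes in the GFP+ EpCAM- sort was not tested. Interferon, cell cycle and hypoxia lists had medians of 0.45, 0.44 and -0.41, each outside its random range, with no member past the 2-fold rule. In all, 67 genes were higher and 36 lower, of 9100.

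Among GFP- cells more genes passed the 2-fold rule between the EpCAM sorts than among GFP+ cells. Epithelial genes were higher in EpCAM+ cells, 19 of 20 with a median of 3.44, and mammary luminal and milk genes, 9 of 11 with a median of 3.56. All 20 endothelial genes and all 12 pericyte genes were lower, with medians of -5.71 and -6.61, and 13 of 14 fibroblast identity genes, with a median of -4.48. Krt19 was 30.9-fold higher (25.1 to 38.6), Wfdc18 84.4-fold (40.8 to 211) and Ltf, which encodes lactoferrin, 61.0-fold (29.4 to 152). Pecam1 was 71.6-fold lower (51.0 to 104), the pericyte gene Rgs5 109-fold (68.0 to 188) and Col3a1 85.3-fold (55.6 to 138). Skeletal muscle genes were lower in 8 of 9 cases (median -5.03), neutrophil genes in 4 of 6 with 1 higher (median -2.83), macrophage genes in 5 of 13 (median -1.41) and adipocyte genes in 5 of 11 with 1 higher (median -1.30), while basal epithelial genes were higher in 7 of 9 cases (median 2.69).

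Other genes higher in GFP- EpCAM+ cells were Fcgbp at 120.1-fold (33.0 to 996), Krt10 at 56.9-fold (30.7 to 119), Dmbt1 at 51.8-fold (24.9 to 129), Fam25c at 45.5-fold (26.9 to 83.5), Ly6d at 35.8-fold (20.3 to 69.7), Cited1 at 33.2-fold (21.6 to 54.0) and Krtdap at no less than 40.2-fold. Lower were Myl9 at 287-fold (112 to 1057), Serpina1b at 233-fold (99.6 to 720), Pdgfrb at 324-fold (89.2 to 2681), Myh11 at 409-fold (72.9 to 16197), Ndufa4l2 at 286-fold (78.8 to 2371), Cd248 at 285-fold (78.4 to 2361), Meg3 at 251-fold (69.0 to 2078), Gpihbp1 at 133-fold (69.7 to 292), Serping1 at 114-fold (74.6 to 185) and Kcnj8 at no less than 102-fold. By levels across genes, the GFP- EpCAM+ library ranked closer to the GFP+ sorts (rho of 0.93 and 0.91) than to GFP- EpCAM- (0.75). All 6 class II genes were higher (median 2.04), with Cd74 at 4.12-fold (3.87 to 4.38), while 7 of 7 leukocyte genes were lower (median -3.15). In all, 698 genes were higher and 1205 lower, of 9518. Of 8405 genes tested in both EpCAM contrasts, 43 were higher in both and 21 lower in both, where independent lists would share 4.16 and 1.81, and 4 went opposite ways. The epithelial median was lower by 2.03 on the log2 scale in the GFP+ contrast than in the GFP- contrast (-2.03), a difference with no test.

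The GFP contrast among EpCAM- cells held many genes of vascular and stromal lists. All 20 endothelial and all 12 pericyte genes were lower in GFP+ cells, with medians of -7.32 and -7.00, as were 12 of 15 fibroblast identity genes (median -5.40), 11 of 13 macrophage genes (median -5.05) and 7 of 7 leukocyte genes (median -4.47). The endothelial gene Plvap was 216-fold lower (154 to 312), Rgs5 237-fold (128 to 494) and Col1a1 107-fold (74.5 to 159). Hypoxia and glycolysis genes were higher, 8 of 18 with none lower and a median of 1.11, among them Car9 at 21.8-fold (11.7 to 45.9) and Vegfa at 7.99-fold (5.95 to 10.95). Adipocyte genes were lower in 8 of 11 cases (median -4.91), and of 5 mammary luminal genes 3 were higher and 2 lower (median 1.51, which changed sign with no count filter). Pdgfra, listed with fibroblast identity, was 22.0-fold higher (5.86 to 185) in GFP+ cells.

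The genes lowest in GFP+ EpCAM- relative to GFP- EpCAM- cells were the chemokines Ccl4 at 9631-fold (1728 to 380470) and Ccl6 at 1203-fold (411 to 5840), Ccl3 at no less than 1904-fold, the cytokine Il13 at no less than 358-fold, the histamine-forming enzyme Hdc at 592-fold (253 to 1826), Srgn at 629-fold (269 to 1940) and Csf2rb2 at 926-fold (256 to 7652). Gpx3 was 1032-fold lower (353 to 5009), Serpina1b 743-fold (205 to 6144) and Cyp11a1 at least 302-fold. Higher in GFP+ cells were the stromelysin gene Mmp3 at 28.7-fold (17.0 to 52.8), Mettl7b at 23.7-fold (9.05 to 87.9), Rap1gap at 17.7-fold (9.16 to 39.1), Cxcl5 at 14.8-fold (8.83 to 26.7), Tns4 at 12.8-fold (9.66 to 17.2), Syt8 at 12.6-fold (9.30 to 17.6), Spp1 at 11.6-fold (10.8 to 12.5), and Lgr6 and Saa2 at no less than 12.2-fold and 11.1-fold. Of the immediate early and dissociation list 7 of 18 were lower (median -0.78). Epithelial genes had a median of 1.09 with 3 of 17 higher, among them Krt18 at 4.10-fold (3.77 to 4.47). In all, 530 genes were higher and 1346 lower, of 9551. Total counts alone moved the median log2 ratio of all genes from 0.03 to 0.15.

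Among EpCAM+ cells the GFP contrast was mostly a set of genes lower in GFP+ cells. It compares 2 sorts and was not shown to be tumour against normal epithelium. Levels in the 2 libraries correlated across genes at a Spearman rho of 0.93, and whether the GFP- sort held tumour cells was not tested. Mammary luminal and milk genes were lower in 8 of 11 cases (median -3.41), with Wfdc18 and Trf at no less than 380-fold and 170-fold and the growth factor gene Areg at 5.51-fold (4.89 to 6.23). Macrophage genes were lower in 8 of 10 cases (median -2.33), with C1qa at 5.43-fold (3.49 to 8.75), endothelial genes in 4 of 9 (median -1.80) and adipocyte genes in 4 of 8 (median -1.88). Epithelial genes had a median of -0.58 with 6 of 20 lower, among them Krt19 at 7.95-fold (7.32 to 8.65). The imprinted transcript H19 was 7.36-fold higher (6.02 to 9.08), Cxcl5 4.49-fold (3.22 to 6.43), Mmp13 2.66-fold (2.29 to 3.11) and Car9 2.87-fold (2.23 to 3.74).

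The other genes lowest in GFP+ EpCAM+ cells were Gpx3 at 699-fold (273 to 2568), Apod at 706-fold (126 to 27955), Dmbt1 at 699-fold (125 to 27655.5), Cited1 at 449-fold (153 to 2179), and Fam25c, Ptn, Igfbp5 and Upk3a at no less than 409-fold, 203-fold, 156-fold and 120-fold. Also higher were Peak1 at 3.59-fold (2.52 to 5.25), Fndc3a at 3.49-fold (2.47 to 5.06), Arl4c at 3.38-fold (2.57 to 4.51), Tns3 at 2.78-fold (2.21 to 3.53), Ccbe1 at 2.77-fold (2.25 to 3.44) and Cd47 at 2.39-fold (2.17 to 2.64). In all, 20 genes were higher and 386 lower, of 9241. Total counts alone gave 32 and 357 genes and moved the median log2 ratio of all genes from 0.01 to 0.14.

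**Figure D3:**
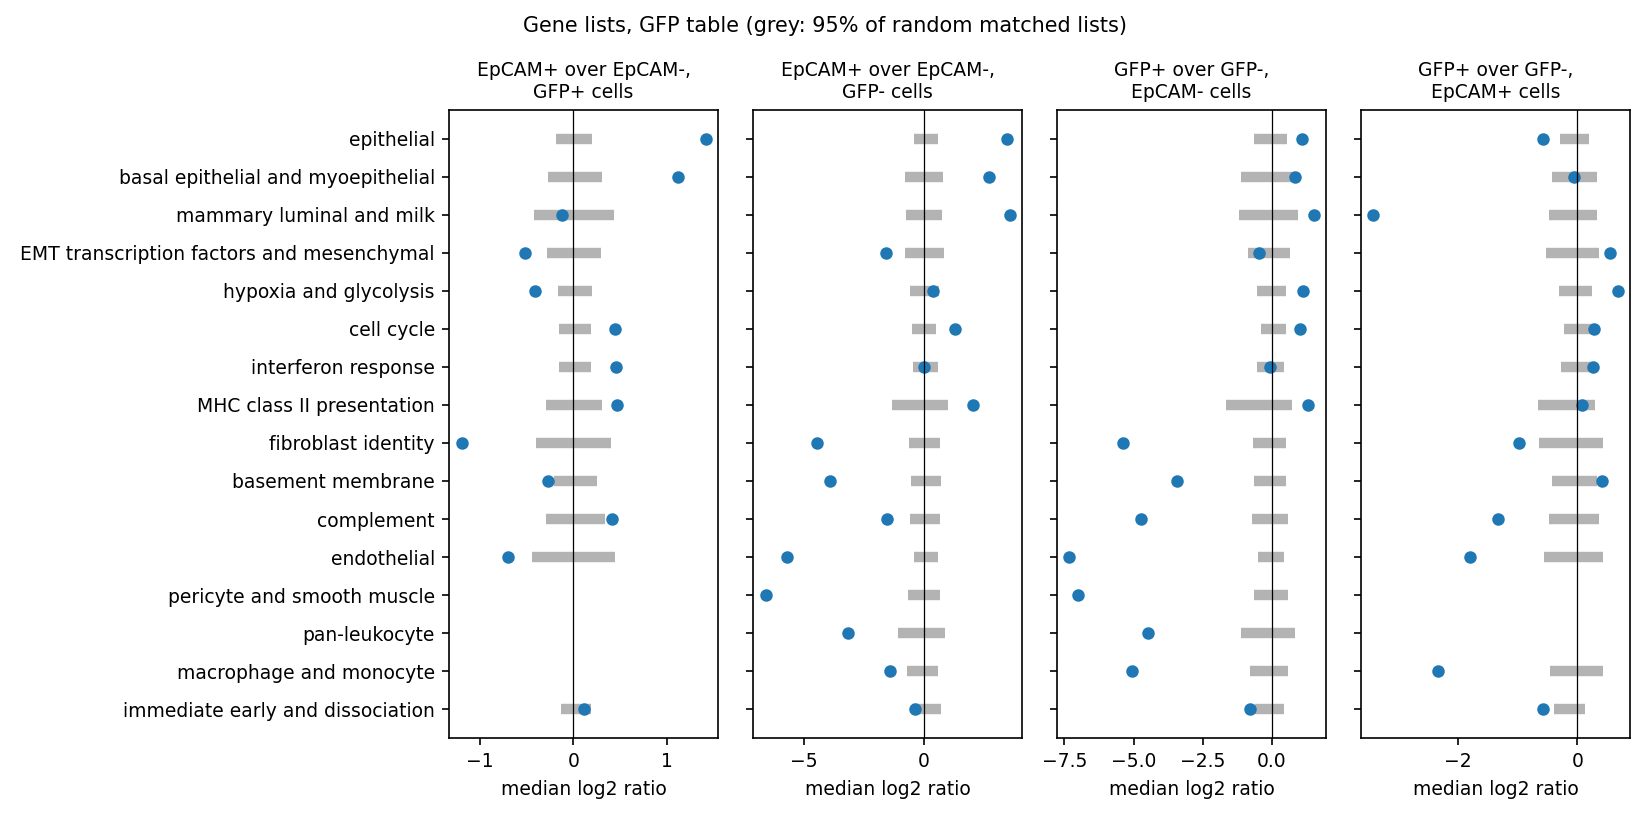
Median log2 ratio of each gene list (points) in the 4 contrasts of the second table, with the central 95% of random lists of the same size matched on expression (grey bars); lists with fewer than 5 measured members have no point, and the horizontal scales differ. The epithelial list lay at 1.41 and 3.44 in the EpCAM contrasts and at 1.09 and -0.58 in the GFP contrasts.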

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

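All tests of explanations in this part were chosen after the result was seen. The lists below moved in opposite directions under the same contrast, each beyond random matched lists. With 1 library per group these differences were not tested.

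In pCAF and sCAF relative to NMF, the medians of the matricellular, matrix enzyme and contractile lists lay higher in pCAF by 4.14, 3.60 and 4.23 on the log2 scale. In the GFP contrast, the basement membrane list lay higher by 3.85 among EpCAM+ than among EpCAM- cells, and the epithelial and mammary luminal lists differed by -1.67 and -4.92. In the EpCAM contrast, the complement and steady-state fibroblast lists lay higher by 1.98 and 2.94 among GFP+ than among GFP- cells. The last 2 and the mammary luminal difference rest on few genes: at least 1 of their medians changes sign with another count filter.

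The sCAF library had little fibroblast RNA and much epithelial and cell cycle RNA. Genes higher in GFP+ than in GFP- EpCAM- cells by the 4-fold rule, a set taken from the other table, had a median log2 ratio of 3.91 in sCAF relative to NMF (68 of 91 higher), beyond random lists (-0.12 to 0.55), which is consistent with malignant 4T1 cells inside the PDPN- EpCAM- gate or a tumour-cell library under this label; the same set was at 0.86 in pCAF, also beyond its random range, where genes higher in the GFP- EpCAM- cells were at -1.12 (193 of 612 lower and 68 higher, random range -0.27 to -0.04). For a small spill of tumour RNA onto stromal cells, genes higher in the GFP- EpCAM- cells by the same rule were examined. They had a median of -3.77 and an upper quartile of -2.17. NMF and the GFP- EpCAM- cells were not split by podoplanin, so the PDPN- gate itself could lower fibroblast genes of this set. The set alone therefore does not decide against a spill onto podoplanin-negative cells. That test replaced a comparison of 4 stromal lists, whose highest median, for macrophages, was -1.09 against a bound of -1 and so decided little. Host cells with Xist at the level of the other stromal libraries, with or without a small spill, are argued against. Xist had 11 counts in sCAF, and the upper end of its ratio to pCAF was 0.0927. Podoplanin-negative host cells as a minor part of this library stay open: Xist had 0 counts in GFP+ EpCAM- cells, endothelial genes were lower in pCAF than in sCAF (median -2.40, random range -1.36 to 0.24), and Pecam1, Plvap and Egfl7 stood at 104, 148 and 79.9 CPM in sCAF and at 9.13, 16.3 and 23.5 in GFP+ EpCAM- cells, in tables scaled separately, while a true difference between the CAF groups was not tested.

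Inflammatory fibroblast genes were higher in pCAF than in NMF, and immediate early genes were too, with a median of 1.33. Tissue dissociation cannot be told apart from the tumour, because fat pad and tumour were digested differently. A higher share of fibroblasts under the PDPN+ gate would lift fibroblast genes alike, but the upper quartile of the fibroblast identity list was 1.04, below the inflammatory median of 3.62. That list holds the sort marker Pdpn itself, 11.7-fold higher (8.93 to 15.6). These values speak only to an even rise of all fibroblasts. Selection by the gate of those fibroblasts that are rich in inflammatory genes stays open and was not tested. A response to the tumour, and the difference in age, may also account for the rise of inflammatory genes and were not tested. Nor was a tumour-cell source tested directly. Relative to NMF, the tumour-cell set was at 0.86 in pCAF and 3.91 in sCAF, and the inflammatory list at 3.62 and 1.16. For that list as a whole, in these single libraries, the values argue against a share of RNA like that of sCAF. Such a share could not raise pCAF above sCAF.

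Leukocyte products stood out in the GFP- EpCAM- library, from cells sorted as CD45-. Basophils or mast cells inside that gate stay open as a source and were not settled: of the 13 genes of their list not already named, 11 (84.6%) were higher there than in GFP+ EpCAM- cells, led by Il4, Mcpt8 and Gata2 at 289.8, 219.9 and 195 CPM, but the counts of most of these genes had been seen when the list was written, so this share decides nothing. Free RNA in a digest shared by the 4 sorts is argued against, a reading fixed after its value was known, as the summed level of the list in GFP+ EpCAM- cells was 0.220% of that in GFP- EpCAM- cells; the labels do not say that the sorts shared a digest, and free RNA in a separate one stays open. Of all 15 genes on the list, 0 are on another list used here and 1 had at least 20 counts in the normal fat pad library. No biological explanation was tested.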

How the results depend on the processing

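The alternatives without sCAF, without the vascular, nerve, muscle and fat lists, and with thinned libraries were chosen after the data were seen. DESeq2 factors and leaving out ribosomal protein genes kept every count within 1.5 times. Without sCAF, TMM gave 616 and 643 genes for pCAF versus NMF, since the relative size of pCAF and NMF stayed at 0.326. TMM scales each library to a single reference, so a size that does not change is little of a check. DESeq2 factors without sCAF gave 625 and 622, and leaving out the lists 612 and 606. The counts against and within sCAF cannot be had without it. Of the list medians under the settings, 849 stayed within the median counting error of their members, 61 moved and 11 reversed; of the gene ratios under other scalings, 547 stayed within their counting interval or within 0.1 on the log2 scale, and 8 moved.

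In the order pCAF versus NMF, sCAF versus NMF, pCAF versus sCAF, EpCAM in GFP+, EpCAM in GFP-, GFP in EpCAM- and GFP in EpCAM+, counts beyond 1.5 times are given as higher or lower. The 4-fold rule gave 232 higher and 173 lower, 566 higher, 242 lower, 20 higher and 8 lower, 214 higher and 702 lower, 97 higher, and 1 higher and 235 lower, and for genes shared against NMF 70 higher and 115 lower; it counts fewer genes by construction. At least 100 counts gave 327 higher and 332 lower, 763 lower, 419 higher, 37 higher and 17 lower, 438 higher and 632 lower, 635 lower and 116 lower, and for the shared genes 115 higher and 233 lower, from fewer genes tested. No filter gave 1784 higher for pCAF versus sCAF and 600 lower for GFP in EpCAM+, from more genes tested. For pCAF versus sCAF these settings moved the share of higher calls to between 33.5% and 74.1%, from 50.5%. Total counts gave 32 higher for GFP in EpCAM+. That setting leaves out the TMM factors, 1.04 for GFP+ EpCAM+ and 0.952 for GFP- EpCAM+, which raises every ratio of this contrast. Thinned libraries gave 419 lower for pCAF versus NMF, 682 higher and 918 lower for sCAF versus NMF and 544 lower for pCAF versus sCAF: depth limits these counts.

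Reversed medians followed the genes a filter let in or out. With no filter the mammary luminal list was at -0.999 for sCAF versus NMF, 0.99 for pCAF versus sCAF and -0.11 for GFP in EpCAM-, the basal epithelial list at -0.27 for GFP in EpCAM-, and the steady-state fibroblast list at -0.18 for EpCAM in GFP+. With at least 100 counts the steady-state fibroblast list was at 0.74 for EpCAM in GFP- and 0.0407 for GFP in EpCAM-, complement at -0.0602 for EpCAM in GFP+ and 0.00399 for GFP in EpCAM+, inflammatory fibroblast at 0.0637 for GFP in EpCAM-, and fibrillar collagens at 0.40 for GFP in EpCAM+.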

Other observations

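The values that follow were picked out after the data had been seen, and no test was made of them. Class II genes were present in tumour-cell libraries as well as stromal ones: H2-Aa stood at 3309 normalised CPM in GFP+ EpCAM+, 2017 in GFP+ EpCAM-, 3077 in GFP- EpCAM+ and 734 in GFP- EpCAM- cells. Spp1 stood at 7073 and 6433 in the GFP+ EpCAM- and EpCAM+ cells, 3943 in GFP- EpCAM+ and 611 in GFP- EpCAM- cells. Xist, the transcript of the inactive X chromosome, had 0 counts in both GFP+ libraries, 82 in GFP- EpCAM- and 37 in GFP- EpCAM+. Its ratio of pCAF to NMF was 1.07 (0.713 to 1.58).

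The TGF-beta list was higher in pCAF than in NMF, 7 of 15 with 1 lower and a median log2 ratio of 0.95 (random range -0.68 to 0.72). The list of proteins folding in the endoplasmic reticulum had a median of -1.08 in sCAF relative to NMF, with 4 of 17 lower and none higher. Class I genes were higher in sCAF than in NMF in 7 of 13 cases, with a median of 1.18 that lay inside its random range (-0.80 to 1.23). Skeletal muscle genes were lower in GFP+ than in GFP- EpCAM- cells in 7 of 9 cases and higher in 1 (median -6.07).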
